A study of Pseudomonas veronii with 6 samples.

How the data were processed

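RNA from 6 samples of Pseudomonas veronii T1 was used, 3 in the aniline group and 3 in the blank group, with groups and replicate numbers taken from the sample titles. Per the labels' protocols, ribosomal RNA was removed and strand-specific libraries were made with dUTP in the second strand. The aligner, the counter, the genome build and the test behind the deposited p-values are not given in the sources used here, nor is the treatment of reads shared between near-identical genes or the use of strand in counting, so genes with close copies or overlapping neighbours on the other strand carry that uncertainty.

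A single table was deposited. Per the file headers it holds raw read counts per transcript, which are whole numbers. A further column per library holds a signal that the authors made by dividing the counts by a single size factor per library, from 0.861 to 1.10, and these are the normalised reads printed in the text. The authors also deposited FPKM values, per the file headers. The library totals that these FPKM values imply are the size factor times the same constant in each of the 6 libraries, so they carry the authors' scaling and not the real depth. The log2 fold changes, p-values and adjusted p-values in the table are the authors', per the file headers. Positions and gene lengths are in base pairs, per the file headers, as other columns.

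The table is a selection. All 472 transcripts have an adjusted p of at most 0.0495 in the authors' deposited table, and the relation of those adjusted values to the p-values implies 6503 tests, of which the listed transcripts are 7.26%. Of the 472, 93 have a gene symbol, 299 a closest Swiss-Prot gene and 422 a product name, among which 30 are hypothetical proteins. A name followed by "-like" or "closest to" is the gene of the closest Swiss-Prot entry in the table, not a gene symbol of this strain.

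The test fixed before the data were examined was limma on log2(FPKM + 1), with edgeR in its place if the table held counts. As it held counts, edgeR 4.0.16 in R 4.3.3 was used (glmQLFit and glmQLFTest, 2-sided, no covariate, trended dispersion). Library sizes were the FPKM-implied totals, which keep the authors' scaling, because TMM on a list of changed genes assumes that most of them did not change. P-values were adjusted by the Benjamini-Hochberg method over 6503 tests, a number chosen from the table before any fit was seen. Genes outside the table would enter at unknown ranks, which makes this adjustment cautious. The dispersion was estimated from selected genes only, which can make it too small. A mean FPKM of at least 1 over all libraries was required, which removed 0 transcripts. The standard error of a log2 fold change is its size divided by the square root of the quasi-likelihood F statistic. The log2 fold changes correlated with those in the authors' deposited table at 0.999997 across genes, which are not independent replicates. As the counts and the scaling were the same, this closeness was fixed beforehand and is no support.

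The named genes follow a rule fixed at the same time. They are the 12 largest rises and 12 largest falls among called and separated genes with a symbol or product, all listed members of the lists for aniline oxidation and for both routes of catechol cleavage, and from each other list up to 2 members with the largest positive and up to 2 with the largest negative log2 fold change, so that a list with all members higher gives no lowest member. The rule gave 59 genes, of which 42 were called. The 24 lists were also fixed beforehand from general knowledge of pseudomonads. A gene belonged to a list by its symbol, its closest Swiss-Prot gene or a phrase in its product name. There were 18 lists with listed members, of which the 9 with at least 3 were tested with camera (preset correlation 0.01, then estimated) and fry from limma 3.58.1, adjusted over the 9 lists. The lists for aniline oxidation, aromatic amino acid and phenylacetate catabolism, nitrogen assimilation, sulfur acquisition, DNA repair and SOS, and type VI secretion had 0 listed members and are not analysed here. As camera compares a list with other listed genes, which were themselves selected, and fry tests genes chosen for having changed, neither is independent evidence. With fry 8 of the 9 lists passed.

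On data simulated for the comparison of aniline with blank, with 472 genes of which 200 were changed, edgeR with the same adjustment called 0 of 272 unchanged genes. It called 5 of 60 genes changed 1.5-fold (8.33%), 26 of 73 changed 2-fold (35.6%) and 66 of 67 changed 4-fold (98.5%). DESeq2 called 0 of 272, 7 of 60, 43 of 73 (58.9%) and 66 of 67. In this simulation edgeR thus missed most changes of 1.5-fold and 2-fold, and DESeq2 most of 1.5-fold. Alternatives comprised DESeq2 1.42.0 with the authors' size factors, limma with pseudocounts of 0.1 and 5, a filter at a mean FPKM of 10 (which removed 43 transcripts), 5 scalings computed on the listed genes, other moderation settings, the replicate number as a block, and each library left out in turn. Chosen after seeing the data were TMM on the listed genes, the use of limma with a pseudocount of 1 (planned as the test for FPKM) as an alternative to edgeR, adjustment over the listed transcripts alone, leaving out the 50 transcripts without a gene model, and list membership without Swiss-Prot genes. Figures and summaries were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.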

Results

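Transcript abundance in Pseudomonas veronii T1, a bacterial strain that the series describes as degrading aniline, was measured by strand-specific RNA sequencing after removal of ribosomal RNA. There were 6 libraries in 2 groups, with 3 libraries of cells given aniline (200 mg/L) for 3 h and 3 libraries of blank cells without it. Both came from cultures grown in LB, a rich medium, for about 6 to 9 h. The design text of the series says that aniline was added when the nutrients in LB were depleted, which no value here measures. The titles place the blank libraries at hour 0, whereas the design text places their sampling after the 3 h of induction, and the sample descriptions carry a 3 in both groups, so the hour of the blank is not settled. The deposited table lists 472 transcripts, of which 422 carry a locus tag and 50 carry no annotated gene model. In the authors' deposited table every listed transcript has an adjusted p-value of at most 0.0495, so the list is a selection of changed transcripts, and genes outside it are not analysed here. Reads in the listed transcripts numbered 1451409, 1518147 and 1353650 in blank replicates 1 to 3 and 1975592, 2352676 and 1942000 in aniline replicates 1 to 3, with a median of 367 reads per transcript and library. These are sums over a selected list, and the full depth of the libraries is not known. The labels do not say that replicates were separate cultures, so the p-values measure only the spread between these libraries.

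The comparison asks which transcripts differ between cells of this strain given aniline and cells without it. The largest fold changes lay in a 17.7 kb region holding genes that resemble the dmp genes of phenol and catechol breakdown. The 3 genes with the largest fold changes there were those closest to dmpL, dmpM and dmpK of phenol hydroxylase, the enzyme complex that adds a hydroxyl group to phenol. The dmpL-like VPH48_RS35080 rose from 20.05 ± 6.89 normalised reads in blank to 14634 ± 3179 with aniline (mean ± SD, n = 3 each), 721-fold. Also higher were 11 called genes of iron acquisition and 4 called genes of chemotaxis, by about 2 to 7 times. On the lower side were 3 single genes of pyrimidine breakdown and 2 of lactate oxidation, groups that were noticed among the falls and not tested as lists, and among ribosomal protein genes rpsG.

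In total 103 transcripts passed the edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, with 85 higher and 18 lower with aniline. Of these, 82 were at least 2-fold higher and 16 at least 2-fold lower. In all 103 the 3 aniline values lay on the same side of the 3 blank values. Among the 472 listed transcripts 453 were separated in this way, against 10% for groups of this size by chance, and all 472 had an unadjusted p under 0.05, as a list selected on these libraries would. A Benjamini-Hochberg adjusted p cannot exceed the largest p in its set. Adjustment over a gene list alone, or over the listed transcripts alone, thus had to pass every member, and the counts given for it are no support. DESeq2 used the same counts and the authors' size factors, and called 395 of these 472 selected transcripts. Its counts within a list are thus no independent support either. Of the 472 transcripts 312 were higher and 160 lower in the authors' deposited table.

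The locus of aromatic breakdown ran from position 7568644 to 7586390 of the genome sequence used in the table (build not given in the sources used here) and held 18 listed genes, all higher with aniline and 17 of them called. Its 15 genes from VPH48_RS35015 to VPH48_RS35085 lie on the minus strand. The 6 genes at the phenol hydroxylase end, from VPH48_RS35060 to VPH48_RS35085 and closest to dmpP, dmpO, dmpN, dmpM, dmpL and dmpK, had log2 fold changes of 7.86 to 9.49, with SE of 0.23 to 0.44. Of these VPH48_RS35065, at 8.29, moved to 8.99 without blank replicate 3. The dmpN-like VPH48_RS35070, which encodes the catalytic hydroxylase subunit, had 19830 ± 2524 normalised reads (not corrected for gene length) with aniline against 63.6 ± 10.7 in blank (mean ± SD, n = 3 each).

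The list of catechol meta-cleavage, the route that opens the catechol ring beside its hydroxyl groups and ends in pyruvate and acetyl-CoA, had 9 listed members in this locus. All 9 rose and were called, and adjustment over the list alone had to pass them. The dmpB-like VPH48_RS35050, the ring-opening catechol dioxygenase, rose by 8.57 on the log2 scale (SE 0.29), from 14.8 ± 4.02 to 5690 ± 818 normalised reads (mean ± SD, n = 3 each). Its neighbours, the ferredoxin gene closest to xylT and the dmpC-like semialdehyde dehydrogenase gene VPH48_RS35045, rose by 8.42 (SE 0.30) and 6.25 (SE 0.30). The 6 genes that follow, VPH48_RS35040 to VPH48_RS35015 (dmpD to dmpI by closest match), rose by 2.23 to 3.26, with SE of 0.19 to 0.36, and the lowest, VPH48_RS35015, passed in 14 of 22 other settings. In blank these 6 had 22.0 to 136 normalised reads, a range that also holds the 50.1 of VPH48_RS35045. Of the 6, dmpE (VPH48_RS35035), the hydratase of the pathway, went from 86.5 ± 16.1 to 828 ± 54.2 (mean ± SD, n = 3 each). Against the other listed genes the list ranked higher by camera with its preset correlation of 0.01 (adjusted p = 4.28e-11 over 9 lists). The call was lost with an estimated correlation (adjusted p = 0.309 with an estimated correlation).

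**Figure D1:**
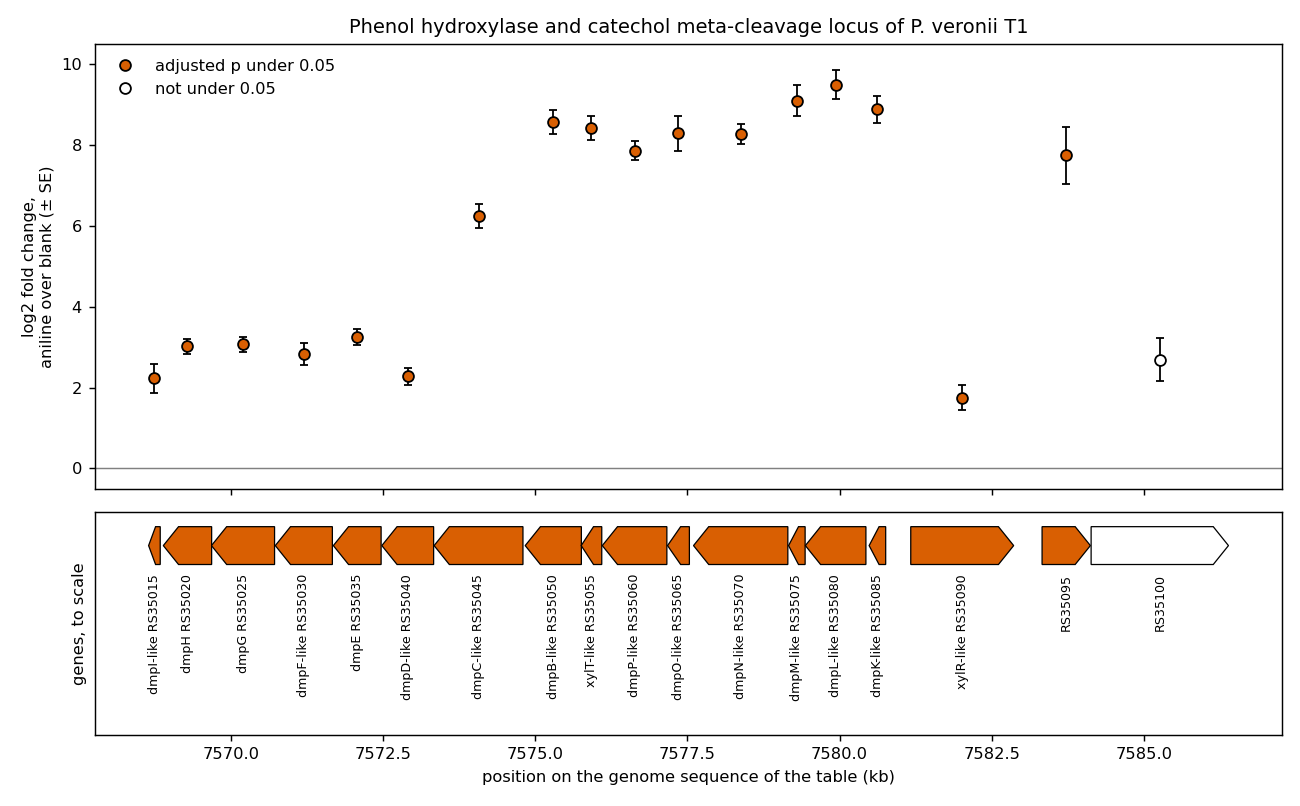
Log2 fold change of aniline over blank with its SE (top, n = 3 libraries per group) and the 18 listed genes of the locus drawn to scale with their strands (bottom), by position in kb. Filled symbols passed the adjusted p threshold of 0.05; the genes from VPH48_RS35045 to VPH48_RS35085 lie between 6.25 and 9.49, and those from VPH48_RS35015 to VPH48_RS35040 between 2.23 and 3.26.

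On the plus strand beside these, the gene closest to xylR, a regulator of aromatic breakdown that works with sigma-54, rose by 1.75 on the log2 scale (SE 0.31). It had 1876 normalised reads in aniline replicate 1, 887 and 874 in replicates 2 and 3, and 343 to 371 in blank. The next gene, VPH48_RS35095, annotated as YCF48-related, rose by 7.74 (SE 0.70), with 3557 normalised reads in aniline replicate 1 and 1054 and 959 in replicates 2 and 3, and by 6.86 without replicate 1. Another pair of genes far from the locus was also among the 12 largest rises, namely VPH48_RS31385 at 5.75 (SE 0.22), a short-chain dehydrogenase closest to bdcA, and VPH48_RS31405 at 5.11 (SE 0.25), closest to the small subunit gene iorA of a molybdenum-containing oxidoreductase. The list of catechol and protocatechuate ortho-cleavage had 1 listed member, VPH48_RS17560, which rose by 2.64 (SE 0.18). It entered through its product name, a carboxymuconolactone decarboxylase family protein, and its closest Swiss-Prot gene is ydfG, so its place in that pathway is not shown. No member of the list of aniline oxidation, the step from aniline to catechol, is among the listed transcripts, and those genes are not analysed here.

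Iron acquisition was the largest list, with 16 listed members, all higher with aniline and 11 of them called by edgeR (16 adjusted over the list alone, 16 by DESeq2). Its median log2 fold change was 1.83. The highest were 2 receptors for siderophores, the secreted iron chelators of pseudomonads, namely fptA-like VPH48_RS15615 at 2.75 (SE 0.24) and fpvA-like VPH48_RS13455 at 2.71 (SE 0.42). The latter passed in 13 of 21 other settings, with log2 fold changes down to 0.75 (quantile normalization). The pvdA-like VPH48_RS20315, an ornithine hydroxylase gene of pyoverdine synthesis, rose by 2.21 (SE 0.23). The exbD gene of the TonB energy system, at 0.68 (SE 0.15), did not pass. These last 2 genes lie outside the rule for naming genes and were picked after their values were seen, as were xylR, srpB, srpC and katE here. The list ranked above the other listed genes by camera (adjusted p = 0.00581), and the call was lost with an estimated correlation (adjusted p = 0.585 with an estimated correlation). The median in aniline replicates 1, 2 and 3 was 2.02, 1.41 and 1.61 above the blank mean on the log2 scale.

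Chemotaxis genes were higher with aniline in 8 of 8 listed members, of which 4 passed the edgeR test (8 adjusted over the list alone, 8 by DESeq2), and 7 of the 8 lie in a single cluster from VPH48_RS10140 to VPH48_RS10190. The cheY-like VPH48_RS10145, a response regulator, rose by 2.04 (SE 0.34) and passed in 12 of 22 other settings, and the cheA-like VPH48_RS10155, the sensor kinase, rose from 162 ± 7.94 to 565 ± 74.0 normalised reads (mean ± SD, n = 3 each). The list did not stand out from the other listed genes (camera adjusted p = 0.218). The 2 flagellar members, flgE at 0.63 (SE 0.18) and VPH48_RS22220 at 0.52 (SE 0.14), did not pass with edgeR (2 passed with DESeq2), and their sign turned under scalings computed on the listed genes.

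Efflux genes went both ways. Of 10 listed members 4 rose, 1 fell and 5 were not called by edgeR (10 passed when adjusted over the list alone, and 10 with DESeq2). The genes srpA, srpB and srpC, which encode the 3 parts of a solvent efflux pump, rose by 1.82 (SE 0.28), 1.24 (SE 0.19) and 1.05 (SE 0.19), and the macB-like VPH48_RS20330 rose by 1.33 (SE 0.24). In other settings srpA passed in 13 of 22, with log2 fold changes down to 0.46, and VPH48_RS20330 in 7 of 21, down to 0.03 with quantile normalization. The small multidrug transporter gene sugE fell by 1.03 on the log2 scale (SE 0.18) and passed in 16 of 22. The list did not stand out by camera (adjusted p = 0.979), and under quantile normalization its median turned from 1.09 to -0.16.

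**Figure D2:**
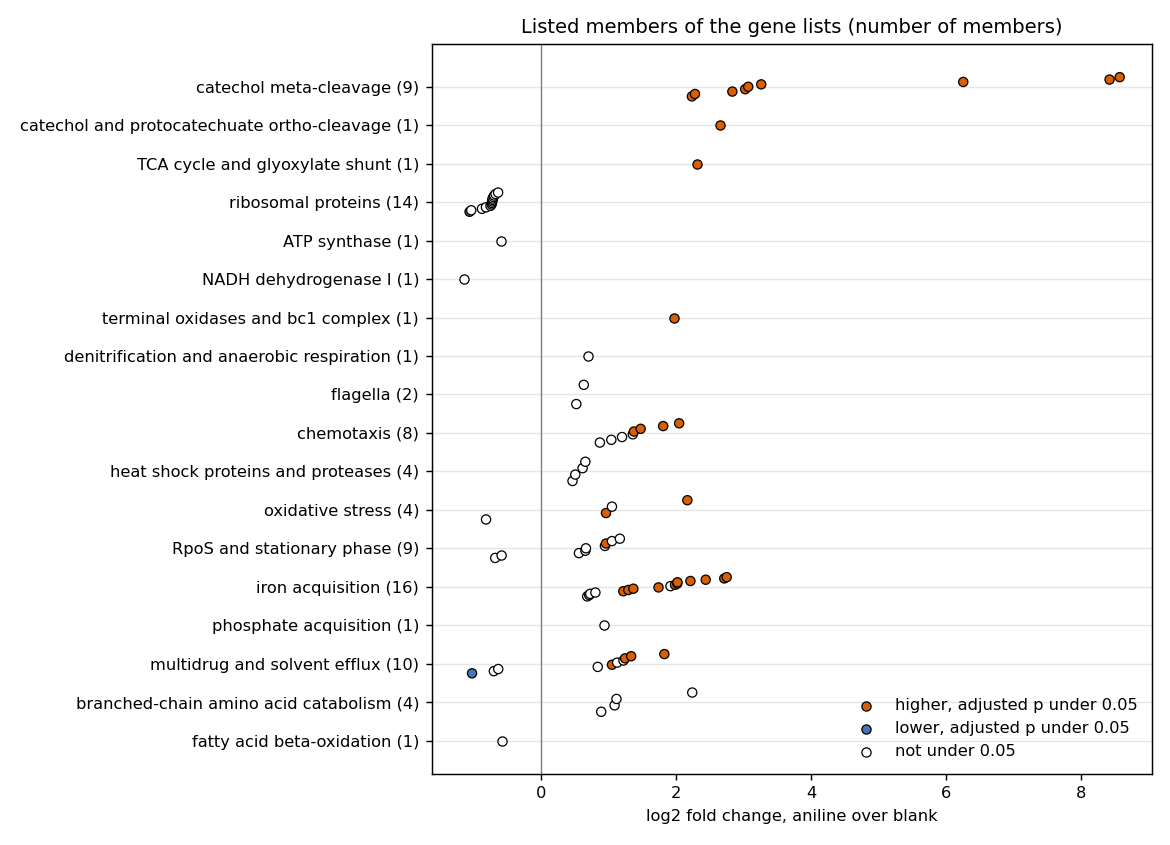
Log2 fold change of aniline over blank for each listed member of the 18 gene lists with members, with lists fixed beforehand. Each point is a gene, coloured where it passed the adjusted p threshold of 0.05, with the number of members after each name; all 9 catechol meta-cleavage and all 16 iron acquisition members lie above 0, and all 14 ribosomal protein members below 0, while flagella, nitrate reductase, heat shock and efflux turned in sign under scalings computed on the listed genes.

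The ribosomal protein list had 14 listed members, all lower with aniline, with a median log2 fold change of -0.73 and 13 of 14 separated. With edgeR 1 member passed, rpsG, a small-subunit protein gene, which fell from 7376 ± 903 to 3529 ± 297 normalised reads (mean ± SD, n = 3 each). With DESeq2 10 of the 14 passed, beside 395 of all 472 listed transcripts, and 14 passed when adjusted over the list alone. The gene rplT had a log2 fold change of -1.04 with an SE of 0.40, and of -0.43 without blank replicate 3, and did not pass (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.46). The list ranked below the other listed genes (camera adjusted p = 0.000356), and the call was lost with an estimated correlation (adjusted p = 0.585 with an estimated correlation). Their median relative to the blank mean was -0.57 and -0.72 on the log2 scale in aniline replicates 2 and 3, and lower than both in replicate 1.

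Respiratory and central metabolic lists had 1 listed member each. The fumC2-like fumarate hydratase gene VPH48_RS04355 of the TCA cycle rose by 2.30 (SE 0.24), and the cydA-like VPH48_RS20620, a subunit of a terminal oxidase used at low oxygen, rose by 1.96 (SE 0.33) but passed in 13 of 22 other settings, with log2 fold changes down to 0.68. The atpH-like gene of ATP synthase at -0.60 (SE 0.16), the nuoA-like gene of NADH dehydrogenase at -1.14 (SE 0.25) and the narG-like nitrate reductase gene at 0.69 (SE 0.22) did not pass with edgeR, while atpH and nuoA passed with DESeq2, and narG also turned in sign under 2 scalings. The other lists with 1 member were phosphate acquisition with ugpC at 0.94 (SE 0.34) and fatty acid beta-oxidation at -0.59 (SE 0.17), neither called by edgeR and the latter called by DESeq2. The latter member is rssB, a response regulator that entered through its closest match atoC.

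Of 4 oxidative stress members 2 rose with edgeR (4 adjusted over the list alone, 4 by DESeq2), the sodA-like superoxide dismutase gene VPH48_RS04365 by 2.16 (SE 0.35), which passed in 14 of 22 other settings, and the catalase gene katE by 0.96 (SE 0.16). The members osmC-like VPH48_RS00255 at 1.05 (SE 0.31) and grxC at -0.82 (SE 0.20) did not pass. In the list of RpoS and stationary phase, the programme of slow or arrested growth, 7 of 9 members were higher and 2 lower, 1 (katE) was called by edgeR and 9 by DESeq2, and all 9 passed adjusted over the list alone. Its extremes were glgE-like VPH48_RS13790 at 1.16 (SE 0.28) and relA-like VPH48_RS31995, a pyrophosphohydrolase gene by product name, at -0.68 (SE 0.18). None of the 4 heat shock members was called by edgeR (4 adjusted over the list alone, 4 at an unadjusted p under 0.05, 4 by DESeq2), with dnaK at 0.61 (SE 0.16) and lon at 0.65 (SE 0.19), and their median of 0.56 turned to -0.12 under the lowest scaling. None of the 4 members for branched-chain amino acid catabolism was called by edgeR either (4 adjusted over the list alone, 4 at an unadjusted p under 0.05, 2 by DESeq2). There mmsB, at 2.24 (SE 0.60), had 1288 ± 1224 normalised reads with aniline and 273 ± 26.3 in blank (mean ± SD, n = 3 each). Aniline replicate 1 carried this value, with 2701 against 628 and 536 in replicates 2 and 3, and without it the log2 fold change was 1.09 and passed. By camera the adjusted p was 0.979 for each of these 4 lists.

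Among the 4 largest falls of called and separated genes were 3 neighbouring genes of pyrimidine breakdown. The dihydropyrimidinase gene hydA (VPH48_RS20035) fell from 209.5 ± 34.7 to 25.2 ± 16.2 normalised reads (mean ± SD, n = 3 each), a log2 fold change of -3.03 (SE 0.44), and of -3.64 without aniline replicate 2. The dehydrogenase genes preA and preT-like VPH48_RS20040 fell by 2.50 (SE 0.42) and 2.33 (SE 0.35) on the log2 scale. Of the 14 named genes called lower 14 passed without aniline replicate 1, 4 and 3 without aniline replicates 2 and 3, and 4, 1 and 3 without blank replicates 1, 2 and 3. The call of hydA was lost without each blank replicate in turn, that of preA without each library but aniline replicate 1, and of these 14 lldD alone passed in every setting. Also among the falls were 2 genes of lactate oxidation, with lldD, an L-lactate dehydrogenase, going from 358 ± 30.3 to 81.7 ± 11.9 (mean ± SD, n = 3 each), and lutA-like VPH48_RS27420 falling by 2.41 (SE 0.43). The remaining 7 of the 12 largest falls, between -1.09 and -1.54, included aroQ of the shikimate pathway at -1.17 (SE 0.17), the argD2-like aminotransferase gene VPH48_RS29460 at -1.54 (SE 0.24) and a biotin carboxylase gene closest to cfiB at -1.30 (SE 0.19). The others were a regulator with an acetyltransferase domain (VPH48_RS16770), an aldolase family gene (VPH48_RS26735), a HAD-family hydrolase gene (VPH48_RS23910) and a dienelactone hydrolase family gene (VPH48_RS15335).

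**Figure D3:**
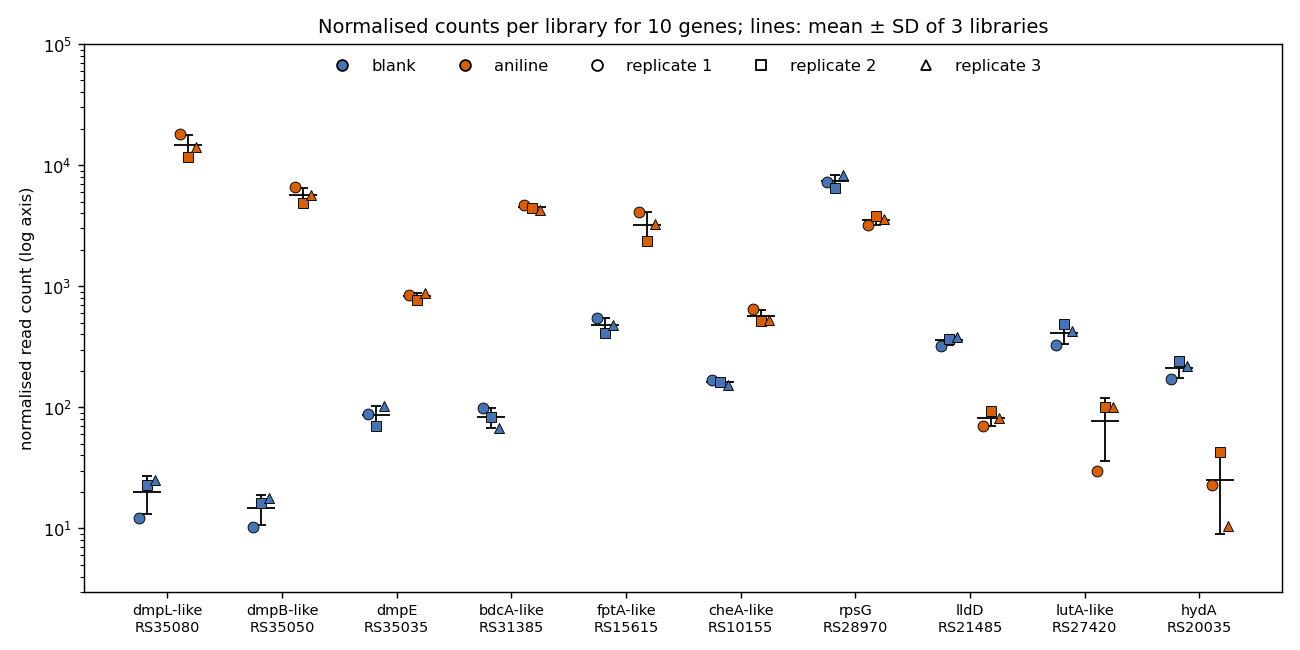
Normalised read counts (log axis) in each of the 3 blank and 3 aniline libraries for 10 genes named in the text and picked for the plot after their values were seen, with the mean and SD of each group. For dmpL-like VPH48_RS35080 the blank libraries lie between 12.2 and 25.3 and the aniline libraries between 11742 and 18039, and for lldD the blank libraries lie between 323 and 381 and the aniline libraries between 70.0 and 93.8.

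The split of higher and lower calls depended on how the libraries were scaled. With the authors' scaling 85 of 103 calls were higher. Scalings computed on the listed genes take most of these selected genes or a total of theirs as unchanged. They gave 51 higher and 152 lower (median of ratios), 54 and 151 (TMM), 49 and 151 (equal FPKM sums), 49 and 151 (sums of listed reads) or 43 and 124 (quantile normalization). The median over transcripts of the shift in log2 fold change was -0.54 to -0.66. The count of calls was 395 with DESeq2 and 472 when adjusted over the listed transcripts alone, the latter fixed by their selection. It was 204, 77 and 55 without aniline replicates 1, 2 and 3 and 52, 42 and 56 without blank replicates 1, 2 and 3, with 42, 7, 3, 4, 1 and 4 lower calls in that order.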

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

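The settings chosen only after the data were seen were TMM on the listed genes, limma on log2(FPKM + 1) as an alternative (it had been planned as the test for FPKM values), adjustment over the listed transcripts alone, leaving out transcripts without a gene model, and lists without Swiss-Prot genes. The main counts were 103 calls, 85 higher and 18 lower, and 98 with at least 2-fold change, 82 higher and 16 lower. Median-of-ratios scaling on the listed genes gave 203, 51 and 152, and with at least 2-fold change 203, 51 and 152. Equal FPKM sums and library sizes from the listed reads each gave 200, 49 and 151, and the same 200, 49 and 151 with at least 2-fold change. TMM on the listed genes gave 205, 54 and 151 for both. Quantile normalization gave 167, 43 and 124, and 153, 39 and 114 with at least 2-fold change. These scalings hold either most selected genes or their total as equal, the total of reads being mostly ssrA and rnpB (56.2% to 68.5% of listed reads), and lowered the median log2 fold change of 0.87 to between 0.12 and 0.32. Of the 103 calls 69, 67, 67, 72 and 58 were shared. DESeq2 gave 395, 259 and 136, and 212, 172 and 40 with at least 2-fold change; the cause was not tested. Adjustment over the listed transcripts alone gave 472, 312 and 160, and 251, 204 and 47. With its smaller number of tests every listed transcript had to pass, as each had an unadjusted p under 0.05. Leaving out a library gave 42 to 204 calls, 41 to 162 higher and 1 to 42 lower, and with at least 2-fold change 42 to 164, 41 to 135 higher and 1 to 29 lower; the highest was without aniline replicate 1 and the lowest without blank replicate 2. Of the 42 named genes called, 42 passed without aniline replicate 1, 29 and 24 without aniline replicates 2 and 3, and 25, 22 and 25 without blank replicates 1, 2 and 3, with 0 changes of sign in any setting. In every setting tried 21 of the 42 passed, 20 higher and 1 lower, the latter lldD. Of all 103 calls 2 turned in sign under quantile normalization, neither of them among the named genes, and 0 in the other settings. Named genes that turned were not called, namely VPH48_RS22220 (-0.12 by median of ratios, -0.14 with equal FPKM sums, -0.14 with listed library sizes and -0.0257 with TMM), flgE (-0.0115, -0.0242 and -0.0298 under the first 3), dnaK (-0.0222, -0.0702 and -0.0665), lon (-0.0341 with equal FPKM sums and -0.0298 with listed library sizes) and narG (-0.00538 with equal FPKM sums and -0.0635 with quantile normalization). The heat shock list turned to -0.0782, -0.12 and -0.12 under the first 3, moving with the median of all genes. Under quantile normalization the efflux list turned from 1.09 to -0.16, further than the median of all genes, which went from 0.87 to 0.12. The pseudocount, moderation and filter settings gave 87 to 110 calls, and the filter at a mean FPKM of 1 removed 0 transcripts, so leaving it out tested nothing. The 3 lists called by camera were called in each setting with its preset correlation, and with an estimated correlation 0 of them were called (adjusted p 0.309, 0.585 and 0.585 in the main setting). With the replicate block the count was 111, 90 higher and 21 lower. Deviations of same-numbered libraries had correlations of 0.17, -0.19 and 0.21, and those of differently numbered ones ran from -0.29 to 0.28. No pairing by number stood out, but 3 libraries per group cannot settle whether the numbers pair the libraries. Depth limits the low side, as some blank means of the locus genes lie under 7 normalised reads, and the full depth is not known.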

Other observations

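All tests in this part were chosen after the results were seen. Listed genes of the same direction within 5 kb of each other formed 16 runs of at least 5 genes, 13 higher and 3 lower, under limits set after seeing the data. A run of 15 genes from VPH48_RS15565 to VPH48_RS15635 had a median log2 fold change of 2.22 and 12 calls. It holds genes closest to pchA and pchB, which make salicylate for the siderophore pyochelin, at 1.98 (SE 0.19) and 2.10 (SE 0.23), peptide synthetase genes at 2.33 and 2.27, and a pair of transporter genes closest to irtA and irtB at 2.37 and 2.38. A run of 8 genes from VPH48_RS13250 to VPH48_RS13285 had a median of 2.02 and 6 calls, with 2 peptide synthetase genes at 2.54 (SE 0.22) and 2.46 (SE 0.25), the PvdF gene VPH48_RS13270 at 2.02 (SE 0.30) and pvdM at 1.74 (SE 0.28), all genes of pyoverdine synthesis by name or position. The fumC2-like and sodA-like genes lie in a run of 5 genes, VPH48_RS04350 to VPH48_RS04370, with a median of 2.16 and 3 calls.

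The short-chain dehydrogenase and iorA-like genes of the report belong to a run of 7 genes from VPH48_RS31385 to VPH48_RS31420, with a median log2 fold change of 3.80 and 4 calls. It adds a DoxX family gene at 4.94 (SE 0.69), or 6.09 without blank replicate 1, and the large-subunit gene closest to iorB at 3.80 (SE 0.23), while the transporter gene VPH48_RS31420 at 2.79 (SE 0.58) did not pass. On the lower side, 6 genes from VPH48_RS27405 to VPH48_RS27435 included 5 for lactate import and oxidation between -1.53 and -2.41, of which the lutA-like gene was called. A run of 10 genes from VPH48_RS09445 to VPH48_RS09540, with transporter genes, gabT and dehalogenase genes, had a median of -1.16, and its lowest adjusted p by edgeR's quasi-likelihood test with the Benjamini-Hochberg method was 0.0716, for the aldehyde dehydrogenase gene VPH48_RS09540.

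The 50 transcripts without a gene model were all higher with aniline, with a median log2 fold change of 1.41, although 4 were called, and against the blank mean their median was 0.51 in aniline replicate 1, 1.89 in replicate 2 and 1.55 in replicate 3. In 18 pairs with a listed gene on the other strand, 17 of these genes were higher with aniline. The median share of the gene's normalised reads was 3.54% in blank and 3.26% with aniline. These medians are not taken within pairs, so they do not show a steady leakage of opposite-strand reads. Within pairs, the log2 ratio to the gene lay above its blank mean in 2, 16 and 14 of the 18 pairs in aniline replicates 1, 2 and 3. Single pairs moved in both directions. The transcript opposite VPH48_RS12115 had a log2 fold change of 1.54 and that gene -0.64, and the share went from 11.1% to 50.1%. Opposite VPH48_RS31385 the share went from 43.8% to 2.92%. The 32 transcripts outside these pairs were also higher, with medians of 0.45, 1.72 and 1.38 above the blank mean in aniline replicates 1 to 3. Leakage at a constant rate is argued against, as the median log2 ratio to the paired gene differed between the 6 libraries by up to 1.59 (permutation p = 1e-05, the smallest that 100000 permutations give). Genomic DNA in the aniline libraries would add the same FPKM everywhere. In all 3 aniline libraries 10 of 422 annotated transcripts lay under 7.27, the lower quartile of the FPKM increase of the 50. Some of the 50 themselves rose by less than their lower quartile, so this cannot exclude genomic DNA, which stays open. A rate of opposite-strand reads that differed between libraries may account for the spread within the aniline group, and stays open for the rise as well. With pair and library means taken out, the transcripts of the 18 pairs followed the gene on the other strand with a slope of 0.81 (SE 0.12, 95% interval 0.56 to 1.06). The slope was 0.73 to 0.91 with any 1 pair left out, and without the pair of VPH48_RS27025 its 95% interval was 0.38 to 1.08. The SE takes the pairs as independent, although several of the genes lie in the run from VPH48_RS15565 to VPH48_RS15635, so it may be too small. For the 32 transcripts outside the pairs this was not tested. Antisense transcription that moves with the gene on the other strand was not tested and would look alike.

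Aniline replicate 1 stood apart from the other aniline libraries. The SD over transcripts of its log2 difference from replicates 2 and 3 was 0.77 and 0.69, against 0.31 between replicates 2 and 3 and 0.40 to 0.58 between blank libraries. With the 50 transcripts without a gene model left out, it was 0.64 and 0.61, against 0.30 between replicates 2 and 3. Between blank libraries it was then 0.37 to 0.58, so the widest blank pair came close to replicate 1. A blank library under an aniline label is argued against by the 15 genes from VPH48_RS35015 to VPH48_RS35085, whose median in it was 7.82 above the blank mean on the log2 scale. The share of reads in the abundant RNAs ssrA and rnpB also differed, at 56.2% of listed reads in replicate 1 against 68.5% and 66.6% in replicates 2 and 3. Such a share would move all other transcripts by a common factor, which hardly changes an SD of log2 differences. As the whole cause of the pattern it is thus argued against. The medians of the 9 tested lists in replicate 1, less the mean of replicates 2 and 3, did not move by a common factor either. They spanned 1.52 on the log2 scale (permutation p = 0.0001, the smallest that 10000 permutations give), from -0.35 for ribosomal proteins to 1.16 for branched-chain amino acid catabolism. No biological explanation was tested, and a culture at another growth stage stays open.

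The lower ribosomal protein genes, with a median log2 fold change of -0.73 over 14 members, may reflect a longer time in culture of the aniline libraries instead of aniline. The titles give hour 0 for blank and hour 3 for aniline, and no blank library is titled hour 3, although the descriptions of both groups carry a 3 that may be the hour. If the titles hold, time and aniline cannot be told apart for these genes or for any other listed transcript. If the design text holds and both groups were taken after 3 h, time would not differ. An effect of aniline itself stays open and untested.

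The 6 libraries can be split into 2 groups of 3 in 10 ways. The real split gave 103 calls and 98 with at least 2-fold change, and only 1 of the 10 splits, the real one, gave as many, with 0 calls by edgeR as the highest of the others. The listed transcripts were selected by the authors on the real split of these libraries, which fixed this outcome beforehand, and with 10 splits a share under 0.05 is out of reach.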
